A study of Homo sapiens with 6 samples.

How the data were processed

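Total RNA of 6 cultures was extracted with a column kit, converted to double-stranded cDNA with a T7-linked oligo(dT) primer and transcribed into biotin-labelled cRNA for hybridisation to Affymetrix arrays, per the labels' protocols. The design text names 3 biological replicates of SHH-stimulated and 3 of unstimulated cells, and the submitters' readme calls the unstimulated group vehicle. Sample groups and replicate numbers were taken from the sample titles. No source used here ties a replicate number to a shared day or batch, and no batch is recorded, so batch could not be examined.

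The deposited value table gives 1 intensity per probe set and array on a linear scale, made by the authors. The 2% trimmed means of the arrays lie between 498.1 and 498.2, so that the arrays appear to be scaled to a common level; image analysis, probe summary, scaling and array design are not given in the sources used here. The table holds 54613 probe sets and no detection calls or control probe sets. The median signal per array was between 94.4 and 111 and the largest value between 30242 and 35610. The authors' deposited comparison, a Cyber-T test of SHH against vehicle per the deposited readme, gives for every probe set a t statistic, which is a score without fixed range, a log2 fold change, a p-value and a q-value. Per the file headers its direction is untreated minus SHH, and the sign was turned here so that positive means higher with SHH. The authors' p-values match a 2-sided t distribution on 4 degrees of freedom within 4.92e-08, their deposited log2 fold changes equal differences of mean log2 intensity without a pseudocount within 4.97e-08, and the per-array intensities behind them are the values of the value table. No column of per-sample values was left unused.

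Gene names came from the authors' deposited table of 2411 probe sets at p at or under 0.05, which carries an array annotation symbol and a symbol chosen by the authors; its annotation release is not given in the sources used here. A probe set took a name where it had 1 symbol and the 2 columns did not disagree, which held for 2142 probe sets of 1640 genes. A further 107 have only the authors' symbol with a mark for an intronic or flanking position, 54 have names that disagree, 10 several symbols and 98 none. Symbols were brought to current use through the synonyms of the RefSeq gene table of GRCh38.p14: 1464 were current, 419 were updated and 259 were kept as given. No coordinates are given, because no genome build is named for the arrays. The brightest named probe set over the 6 arrays stands for a gene. Of 350 genes with more than 1 named probe set, 348 had all of them in the same direction, and CDC42 and FYN, named after their values were seen, did not. Only probe sets at p at or under 0.05 in these samples could be named. Unchanged probe sets are thus left out, and this count cannot show how far all probe sets of a gene agree. Probe sets outside the deposited table of 2411 are unnamed here, so a gene without a name here can still be on the arrays. Likewise, a named gene can have unnamed probe sets that are unchanged or brighter than the one that stands for it.

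SHH was compared with untreated by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 2-sided, Benjamini-Hochberg adjustment over 54613 probe sets, threshold 0.05) on log2(intensity + 16). A fold change is on that scale and understates the change of dim probe sets. The SE given after a log2 difference is limma's moderated SE, which draws on the spread of all probe sets. It is not the spread of that gene's replicates alone. No filter was applied. The test had been planned per gene over genes with 1 symbol; because most probe sets are unnamed here, it was run per probe set. For the same reason the planned set tests camera and fry, the count of calls adjusted over the list alone, the mean of all probe sets of a gene and the comparison of 3' and 5' control probe sets could not be run. Instead, the named members of the 36 lists fixed before the data were examined (29 functional lists, 6 of cell type markers and 1 of housekeeping genes) were counted by direction, and the direction was set against that of the other named genes by Fisher's exact test with adjustment over the lists that had a named member (Python 3.11.15, scipy 1.17.1, pandas 2.3.3). This test was chosen after seeing the data.

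The text names, by a rule fixed before the data were examined, the 12 genes per direction with the largest log2 difference past the threshold, apart on all arrays and brighter than the median (filled with genes at an unadjusted p under 0.05), every named hedgehog target, up to 3 members of each other list by smallest p and the leading 3 genes per direction of the authors' lists. This gave 109 genes, of which 26 passed the threshold; a few of the others are not reported here. Genes named outside the rule are said to be so where they are named.

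The fit was tested on simulated arrays of 54613 probe sets with 100 changed at each of 2 sizes. With a log2 change of 1 it recovered 0 of 100, and with a log2 change of 2 it recovered 40 of 100. With an intensity trend it recovered 40 and 66, and both fits made 2 false calls. The simulated spread followed a smooth trend with signal, the form that the intensity trend assumes, and was on average wider than that of the arrays. All changes were placed in probe sets at or above the median signal. The simulation therefore cannot rank the fits for these data or give their power here. The alternatives were the replicate number as a block, filters at the median and the lower quartile of mean signal, quantile normalization, centring of each array on its median, pseudocounts of 1 and 64, an intensity trend in the variance with and without robust estimation, array weights, a plain equal-variance test per probe set, and each array left out in turn. The intensity trend as a base for further alternatives was added after seeing the data.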

Results

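Expression was measured on 6 single-colour Affymetrix arrays of CCD-18Co cells, an established line of colon fibroblasts described by the submitters as myofibroblasts. The cells were kept in medium with 0.1% bovine serum albumin. SHH (sonic hedgehog, a secreted ligand of the hedgehog pathway) was given at 1 ug/ml for 72 h to 3 biological replicates, and 3 replicates were left untreated. No culture time is recorded for the untreated cells, so whether they were kept as long is not known. Each array gave a signal for 54613 probe sets, with medians between 94.4 and 111 and trimmed means between 498.1 and 498.2. The number of arrays limits the precision of every value. Gene names were at hand for 1640 genes, all of them represented by probe sets with an unadjusted p at or under 0.05 in the authors' deposited table, so the lists of named genes were chosen on these same samples and their directions are not independent evidence. The value given for a gene is that of its brightest probe set named in this way. Unnamed probe sets of the same gene can be brighter or unchanged.

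The comparison of SHH-treated with untreated cells asks which transcripts respond to the hedgehog ligand in colon fibroblasts. Transcripts of the hedgehog receptor PTCH1, itself a classical target of the pathway, rose 6.25-fold. The log2 difference was 2.64 ± 0.11 (limma's moderated SE, n = 3 per group, limma adjusted p = 0.0249). The ± of other log2 differences is this SE too, which draws on the spread of all probe sets. The forkhead transcription factors FOXF2 and FOXL1, both known from gut mesenchyme, also rose, FOXF2 by 1.32 ± 0.11 on the log2 scale and FOXL1 from a dim signal by an amount that depends on the pseudocount. Among named genes brighter than the median the chemokine CXCL14 rose most, 12.6-fold (3.65 ± 0.23). The matrix glycoprotein tenascin-C (TNC) and the complement component C7 fell most among genes brighter than the median, by 2.10 and 2.07 on the log2 scale.

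Of the 29 genes fixed beforehand as hedgehog targets, 12 had a name here, and 10 of these 12 were higher and 2 lower with SHH. By limma, 3 of the 12 passed the adjusted threshold, all of them higher, and 9 did not. PTCH1 signal was 1368 ± 77.4 in untreated and 8635 ± 414 in SHH-treated cells (SD, n = 3). All 4 of its named probe sets were higher, and 3 of them passed limma's threshold. FOXF2 went from 2940 ± 61.9 to 7393 ± 446 (SD, n = 3; limma adjusted p = 0.0425). FOXL1 was dim in untreated cells, at 7.05 ± 4.47, and reached 128 ± 34.9 with SHH (SD, n = 3; limma adjusted p = 0.0468), and its log2 difference was 2.63 ± 0.23 with the pseudocount of 16, 4.10 with a pseudocount of 1 and 1.42 with a pseudocount of 64. GLI1, the transcription factor that is the standard readout of hedgehog signalling, had a log2 difference of 2.52 ± 0.38, with all 3 SHH arrays above all 3 untreated arrays, from 114 ± 55.8 in untreated to 674 ± 89.9 in SHH-treated cells (SD, n = 3), and it did not pass (limma adjusted p = 0.110, and 0.00355 with an intensity trend). The arrays of the groups did not overlap, in either direction, in 17.3% of all probe sets, where chance gives 10%. BMP2, SFRP1 and RAB34 had log2 differences of 0.87, 0.59 and 0.40 without passing the threshold, and passed limma with an intensity trend at adjusted p = 3.50e-04, 0.00235 and 0.0193. Over all alternatives the adjusted p of these 4 ranged from 3.50e-04 to 0.559. FOXF1 (0.31), NKX2-3 (0.26), WNT5A (0.25), CCND2 (-0.38) and IGF2 (-0.39) passed neither. FOXF1 and NKX2-3 are bright, and all probe sets with a mean log2 signal of 13 or more had a median difference of 0.08. A further probe set, singled out after its value was seen, that only the authors' annotation places 3' of FOXC2, another gene of the list, rose by 2.01 ± 0.10 (limma adjusted p = 0.0423) and was not counted. The median log2 difference of the 12 targets was 0.49. These 12 were named by their p in these samples and the 17 others are left out. It is therefore not the median of the whole list, as had been planned, and can overstate it. Against the other named genes, the direction of the list gave Fisher's exact two-sided p = 0.0219, and 0.351 after adjustment over the lists tested.

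**Figure D1:**
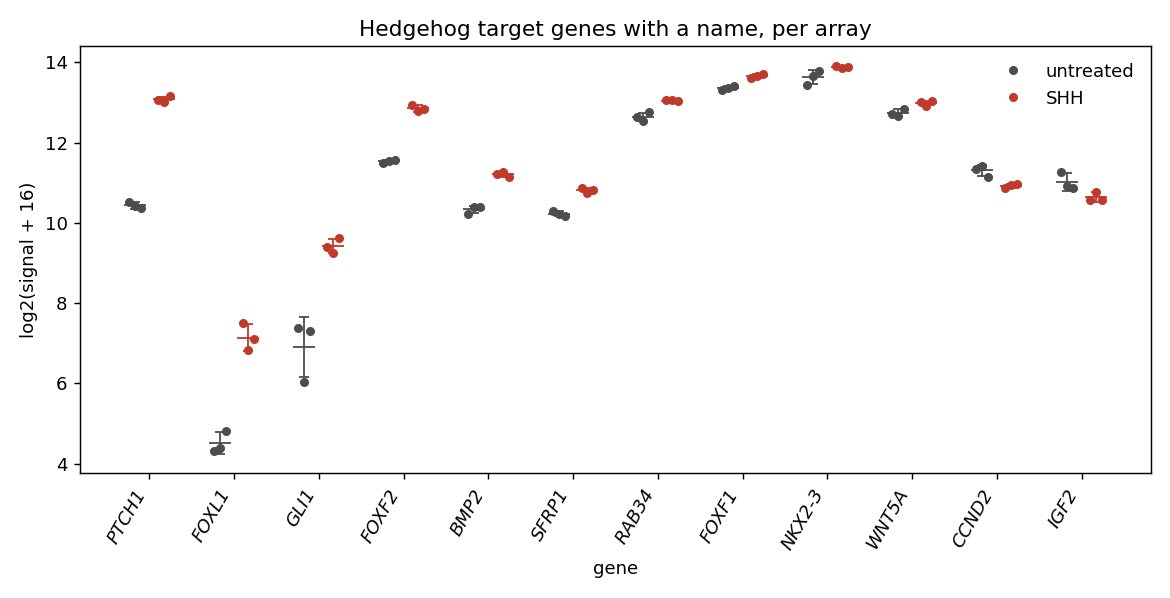
Signals of the 12 named hedgehog targets on a log2(signal + 16) axis, ordered by their difference; points are the 3 arrays of each group, horizontal bars the means and whiskers the SD. The 3 SHH points of PTCH1 lie above its 3 untreated points by a mean of 2.64, while the untreated points of GLI1 are spread apart.

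Among the components of the hedgehog pathway, 5 of 30 genes had a name, 2 higher and 3 lower. The co-receptor GAS1 fell by 1.24 on the log2 scale, from 2386 ± 150 to 998 ± 53.7 (SD, n = 3; limma adjusted p = 0.0468), and the other 4 did not pass. BOC, another co-receptor, had a difference of 0.37 ± 0.11 and GSK3B of 0.52 ± 0.12 (limma adjusted p = 0.362 and 0.266). GLI3 and EVC, named after their values were seen, lay at -0.75 and -0.33. Of the primary cilium list, the compartment in which the pathway signals, 1 of 28 genes had a name, IFT57, at 0.47 ± 0.10 (limma adjusted p = 0.233).

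The 12 named genes that rose most among those brighter than the median were CXCL14, PTCH1, VCAN, DLL4, F2R, LACTB, TGFBR3, NRTN, ST3GAL5, SLC12A8, ABCG2 and RASSF4, with log2 differences from 3.65 down to 1.48. CXCL14 signal went from 183 ± 59.6 to 2419 ± 40.3 (SD, n = 3; limma adjusted p = 0.0423), with both of its named probe sets past the threshold. The proteoglycan versican (VCAN) rose by 1.82 ± 0.15, from 1922 ± 297 to 6815 ± 587, and all 5 of its named probe sets passed limma's threshold. The Notch ligand DLL4 rose by 1.78 ± 0.13 and the thrombin receptor F2R by 1.76 ± 0.12. TGFBR3, the co-receptor betaglycan, rose 3.28-fold, and NRTN, a neurotrophic factor of the GDNF family, rose 3.18-fold. LACTB, a mitochondrial protein, rose 3.36-fold and ABCG2, a drug efflux transporter, 2.87-fold. The ganglioside GM3 synthase ST3GAL5 rose by 1.67, SLC12A8 by 1.65 and RASSF4 by 1.48 on the log2 scale. Of the named probe sets, all higher, 2 of 3 passed for LACTB and 1 of 2 each for TGFBR3 and ST3GAL5. In the order of their statistic, the leading 3 named genes of the authors' deposited list of higher genes were PTCH1, VCAN and LACTB.

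In the other direction, 10 named genes brighter than the median passed the threshold, among them TNC, C7, HAS3, MBP, PRSS35, GAS1, ASPN, GUCY1B1 and NOG. TNC signal fell from 2328 ± 166 to 537 ± 101 and C7 signal from 5745 ± 602 to 1363 ± 199 (SD, n = 3; limma adjusted p = 0.0423 for both). Of the 2 named TNC probe sets, both lower, 1 passed. HAS3, a hyaluronan synthase, fell by 1.76 on the log2 scale, and with TNC and C7 it led the authors' deposited list of lower genes. MBP fell by 1.39, PRSS35 by 1.29 and a dim gene listed as FLJ10521 by 1.32 (limma adjusted p = 0.0496, and 0.0379 with an intensity trend, which gave it a larger unadjusted p). Transcripts of asporin (ASPN), a matrix proteoglycan, fell by 1.23, and those of GUCY1B1, a subunit of the nitric oxide receptor guanylate cyclase, fell by 1.21. Each had 2 named probe sets, all lower, of which 2 passed for ASPN and 1 for GUCY1B1. The BMP antagonist noggin (NOG) fell by 1.07. Not past the adjusted threshold, but with larger differences than several of these, were the eosinophil chemokine CCL11 at -1.73 ± 0.18 (limma adjusted p = 0.0539) and the amino acid transporter SLC7A8 at -1.58 ± 0.34 (adjusted p = 0.228).

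**Figure D2:**
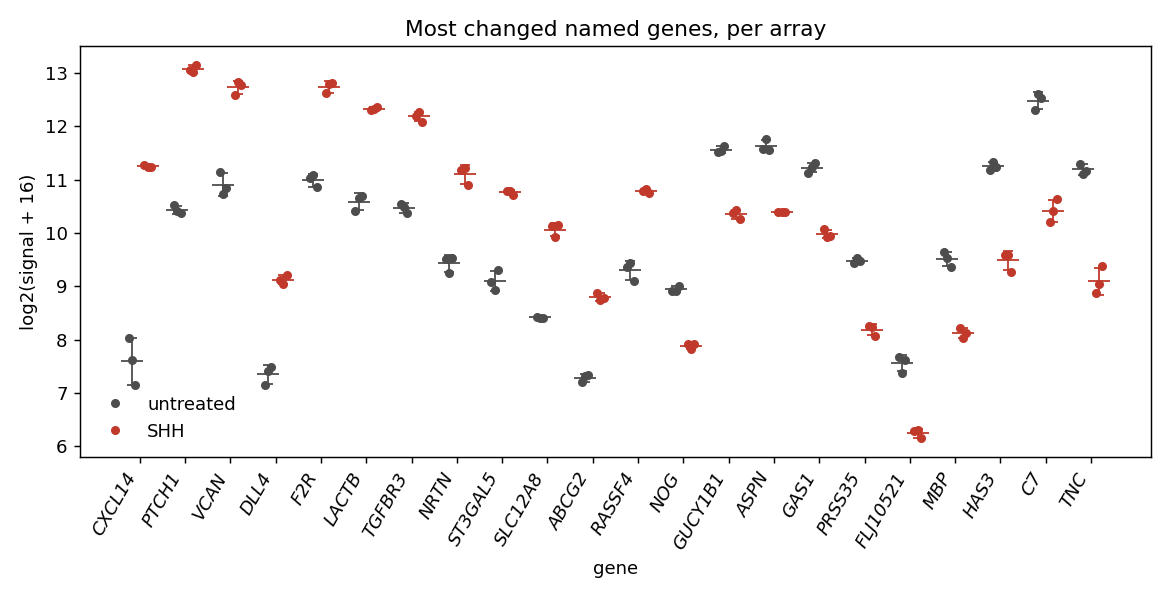
Signals of 22 named genes brighter than the median and past the limma threshold, the 12 that rose most and the 10 that fell, on a log2(signal + 16) axis from the highest difference to the lowest; points are the 3 arrays of each group, horizontal bars the means and whiskers the SD. In all 22 genes the SHH points lie apart from the untreated points, as the rule that chose them required, from CXCL14 at 3.65 to TNC at -2.10.

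Over all 54613 probe sets, limma called 67 changed at an adjusted p under 0.05, 45 higher and 22 lower with SHH, with log2 differences between -2.10 and 3.65 and none smaller in size than 1.06. Of these, 63 carry 1 gene symbol, and they stand for 51 genes. Read by the brightest named probe set of each gene, 41 genes passed, 26 higher and 15 lower. At an unadjusted p under 0.05 there were 5310 probe sets, where chance gives 2731, and 39.1% of them were higher, or 50.3% after quantile normalization and 60.3% with each array centred on its median. With that centring limma called 34 probe sets, 32 higher and 2 lower. The authors' deposited table holds 2411 probe sets at p at or under 0.05, 1235 higher and 1176 lower, with a lowest q of 0.392, and includes all 67. Limma with an intensity trend called 1014 probe sets, 550 higher and 464 lower, which stand for 697 genes and include 64 of the 67; that count was 553 without untreated replicate 2 and 524, 492 and 503 without SHH replicates 1, 2 and 3. No probe set passed limma's adjusted threshold when any 1 of the 6 arrays was left out, with 4411 to 5180 at an unadjusted p under 0.05.

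Of the matrix glycoprotein and crosslinking list, 15 of 30 genes had a name, 7 higher and 8 lower; VCAN rose, TNC and ASPN fell, and the other 12 did not pass. LAMA2 and OGN were named after their values were seen: LAMA2, a laminin chain, had signals of 3250 ± 314 untreated and 1617 ± 144 with SHH (SD, n = 3), OGN (osteoglycin) lay at -1.06 ± 0.12, and the brightest LAMA2 probe set missed the threshold (limma adjusted p = 0.0810) while another of its 3 passed. None of the 10 named collagens of 23 passed, 6 being higher and 4 lower, with COL11A1 at 0.67 ± 0.11, COL4A1 at 0.43 ± 0.11 and COL14A1 at -0.49 ± 0.11. Of the proteases and inhibitors, 5 of 28 had a name, 2 higher and 3 lower, and the urokinase PLAU had the largest difference, 1.05 ± 0.11 (limma adjusted p = 0.0607). PLAUR lay at -0.39. Among fibroblast identity genes 9 of 22 had a name, 2 higher and 7 lower, and none passed; POSTN lay at -0.98 ± 0.14, S100A4 at -0.50 ± 0.10 and PDPN at 0.57 ± 0.14. Contractile genes, 9 named of 25, were 5 higher and 4 lower with none past the threshold, with the smooth muscle myosin MYH11 at 0.94 ± 0.16, SYNPO2 at 0.89 ± 0.11 and SYNM at -0.77 ± 0.13.

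Of the BMP list, 12 of 30 genes had a name, 3 higher and 9 lower; NOG fell and the other 11 did not pass by their brightest probe set. BMP6 lay at -0.91 ± 0.11 and the antagonist GREM1 at -0.97 ± 0.12 (limma adjusted p = 0.0649 and 0.0729), and a dimmer probe set of GREM1 passed. The Notch list had 5 named genes of 24, 4 higher and 1 lower; DLL4 rose, while the ligand JAG1 at 1.16 ± 0.17 and the target HES1 at 1.14 ± 0.14 did not pass by their brightest probe set (limma adjusted p = 0.100 and 0.0757). Of the Wnt list 6 of 32 had a name, 5 higher and 1 lower and none past the threshold, with LEF1 at 1.04 ± 0.14 and FZD8 at 0.59 ± 0.10. The TGF-beta response list had 5 named genes of 27, 1 higher and 4 lower, none past the threshold, with TGFBR1 at -0.48 ± 0.11 and CDKN2B at 0.35 ± 0.10. Of growth and angiogenic factors 15 of 34 had a name, 7 higher and 8 lower; SLIT2, a secreted guidance factor, rose by 1.23 ± 0.12 (limma adjusted p = 0.0496). SLIT2 had 3 named probe sets, all higher, of which 1 passed. VEGFA lay at 0.98 ± 0.11 and PDGFC at 0.93 ± 0.11; the brightest VEGFA probe set missed the threshold (limma adjusted p = 0.0609) and 2 of its 4 passed. Axon guidance and adhesion genes, 10 named of 34, were 2 higher and 8 lower, none passing by its brightest probe set, with NRP1 at -0.88 ± 0.12, SEMA3C at -0.78 ± 0.17 and EPHA2 at -0.46 ± 0.10.

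Of cytokines and chemokines 7 of 30 had a name, 2 higher and 5 lower; CXCL14 rose and the other 6 did not pass, among them CXCL12 at -1.07 ± 0.11 (limma adjusted p = 0.0607). The NF-kB list had 5 named genes of 18, 3 higher and 2 lower, with SOD2 at 0.92, NFKBIZ at -0.59 and VCAM1 at -0.57. The interferon list had 4 of 31, 1 higher and 3 lower, with IFIT1 at -0.65, IFIT2 at -0.63 and GBP2 at 0.56. All 4 named genes of 19 in the prostaglandin list were higher, with the cyclooxygenase PTGS1 at 0.93 ± 0.10, ABCC4 at 0.89 ± 0.11 and PTGES at 0.56 ± 0.13. None of the named genes of these last 3 lists passed limma's adjusted threshold (adjusted p = 0.198, 0.228 and 0.0609 for SOD2, IFIT1 and PTGS1).

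Among genes of proliferation, metabolism and stress, ACAT2, an enzyme of acetyl-CoA metabolism, rose by 1.09 ± 0.10 (limma adjusted p = 0.0496), and no other passed by its brightest probe set. The cholesterol list that holds it had 5 named genes of 25, 4 higher and 1 lower, with SQLE at 0.44. All 4 named of 35 genes of G1/S and DNA replication were higher, with TK1 at 1.21 ± 0.22, RRM2 at 0.50 and TYMS at 0.44, as were all 4 named of 32 mitosis genes, with CCNB1 at 0.99 ± 0.12, TOP2A at 0.59 and KIF23 at 0.56. All 7 named of 22 oxidative stress genes were higher, with the quinone reductase NQO1 at 0.75 ± 0.11, SLC7A11 at 0.72 and SRXN1 at 0.41; Fisher's exact two-sided p for their direction was 0.00765, and 0.260 after adjustment. All 4 named of 24 unfolded protein response genes were higher, with ATF3 at 0.47, SEL1L at 0.40 and ASNS at 0.30. Glycolysis and hypoxia genes, 7 named of 30, were 4 higher and 3 lower, with SLC2A1 at 0.67 and HK2 at -0.60. Heat shock and immediate early genes, 8 named of 24, were 5 higher and 3 lower, with EGR1 at -0.72, EGR3 at -1.06 and KLF4 at 0.57. The p53 list, 4 named of 24, had 2 in each direction, with PMAIP1 at 0.91, FAS at -0.39 and GADD45A at -0.29. SCD at 1.25 and DGAT1 at -0.71 were the 2 named of 23 fatty acid genes, NDUFA4 at 0.25 the 1 named of 30 oxidative phosphorylation genes and RPL5 at 0.98 the 1 named of 30 ribosomal protein genes; a dim RPL5 probe set passed (limma adjusted p = 0.0496, and 0.0264 with an intensity trend).

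Of the markers of other cell types, none of 12 endothelial and none of 9 adipocyte genes had a name. The epithelial keratin KRT18 lay at -0.42 ± 0.11, the monocyte marker CD14 at 0.73 ± 0.25 and the neuronal marker UCHL1 at 0.67 ± 0.10, each the 1 named member of its list, and none of them passed (limma adjusted p = 0.324, 0.437 and 0.109). Of the markers of interstitial cells of Cajal and pericytes, 6 of 11 had a name, 2 higher and 4 lower, with KCNJ8 at -0.88 ± 0.18, RGS5 at -0.66 ± 0.16 and KIT at -0.44 ± 0.11. Of 14 housekeeping genes, TFRC and YWHAZ had a name, both higher, at 0.58 ± 0.23 and 0.42 ± 0.20, and neither passed. Over the 34 lists with a named member, no direction passed Fisher's exact test after Benjamini-Hochberg adjustment, the lowest adjusted p being 0.260, and 2 lists had an unadjusted p under 0.05. Lists with 4 or fewer named members could not pass: 4 of 4 higher gave Fisher's exact two-sided p = 0.0620 before adjustment. With 7 of 7 higher it was 0.00765, and 0.260 after adjustment. Lists that did not pass are thus no evidence of no shift. The test also takes genes measured on the same arrays as independent.

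**Figure D3:**
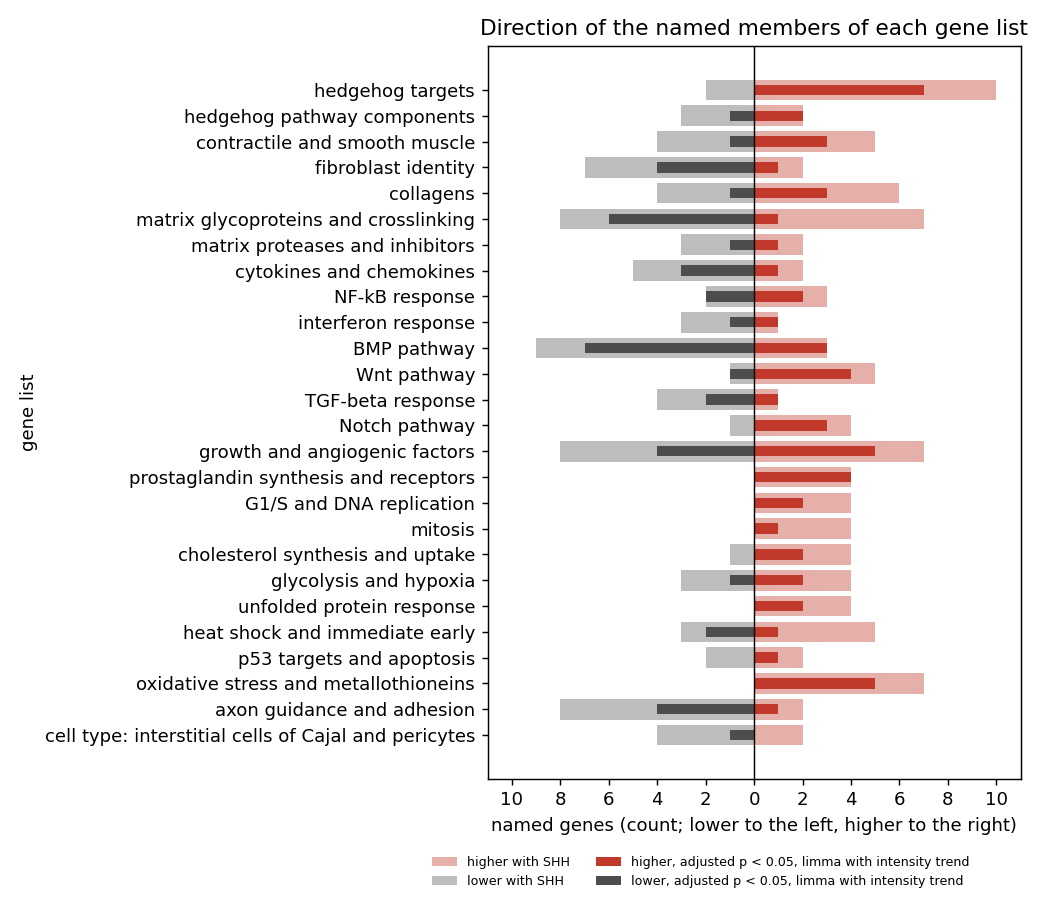
Numbers of named genes that were higher (right) or lower (left) with SHH in each list with at least 4 named genes; wide pale bars count all named genes and narrow dark bars those at an adjusted p under 0.05 in limma with an intensity trend. The hedgehog target list has 10 named genes to the right and 2 to the left, and the BMP pathway list 3 to the right and 9 to the left.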

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

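The settings that build on the intensity trend, the direction test of the lists and the counts over splits of the arrays were chosen after seeing the data, and the other settings before. The count of 67 probe sets past limma's threshold moved to 0 with the replicate block (4746 at an unadjusted p under 0.05), 0 with a pseudocount of 1 (5009) and 295 with a pseudocount of 64, 34 with arrays centred on their medians, 147 by a plain equal-variance test, 1014 with an intensity trend and 905 with its robust form. It was 158 among probe sets at or above the lower quartile of mean signal and 558 at or above the median, where fewer are tested. It was 66 after quantile normalization and 73 with array weights, with 60 and 67 of the 67 kept. Without any 1 of the 6 arrays it was 0 (4411 to 5180 at an unadjusted p under 0.05), with fewer samples fitted and lowest adjusted p between 0.154 and 0.201; elsewhere the cause was not tested. The unadjusted count stayed within 1.5 times of 5310 under every setting, and the lowest adjusted p of the 67 was 0.0249.

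With the intensity trend the 1014 calls were 680 with the replicate block, 1085 after quantile normalization, 1017 and 945 with pseudocounts of 1 and 64, 1500 at or above the median signal, and 492 to 804 without 1 array (553 without untreated replicate 2, and 524, 492 and 503 without SHH replicates 1, 2 and 3). The values show no pairing by replicate number: the deviations of same-numbered arrays correlate at 0.02, 0.01 and -0.04, and not every array correlates best with its own number. Whether same-numbered cultures were handled together is not known. The median of the 12 named hedgehog targets, 0.49, was 0.40 among the 11 at or above the median signal and 0.46 after quantile normalization. It was 0.58 with arrays centred on their medians and 0.47 to 0.51 without 1 array. The cause was not tested beyond the lost member. All these medians rest on members named by their p in these samples. No list passed Fisher's exact test of direction after adjustment in the fit reported, where 2 had an unadjusted p under 0.05; it rests on signs, which settings of the variance leave as they are, so its count of 0 there says nothing of stability. None of the 109 named genes reversed, and no list member changed direction under either scaling. In all 109 the SHH and untreated arrays do not overlap, so apart from quantile normalization and median centring no setting could have reversed them. Their lack of reversal under those other settings says nothing of stability. The 26 past the threshold all lost it with the replicate block, with a pseudocount of 1 and without any 1 array, and 12 did with median centring.

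In 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, limma called 67 probe sets, and the highest of the others was 0; with the intensity trend the values were 1014 and 0, and at an unadjusted p under 0.05 they were 5310 and 3218. With 10 splits no share can fall under 0.05. The gene lists' set tests, the mean of all probe sets of a gene and the control probe sets were not run, as most probe sets are unnamed here and no control probe sets are in the table used. Without detection calls, signal over background is unknown for dim genes.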

Other observations

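The genes singled out in this part and the tests of its 3 patterns were chosen after the data were examined, while the intensity trend, quantile normalization, centring and pseudocounts were fixed before. Besides F2R, the related receptor F2RL2, higher on 3 of 3 SHH arrays, had a log2 difference of 1.76 ± 0.17 and the protein C receptor PROCR, also higher on 3 of 3, one of 1.34 ± 0.14 (adjusted p = 2.09e-04 and 2.10e-04 by limma with the trend), though a dimmer F2RL2 probe set did not pass with the trend (adjusted p = 0.149 by limma). Arrays that do not overlap between the groups, in either direction, are found in 17.3% of all probe sets. Both bradykinin receptors were higher as well, BDKRB1 by 0.67 ± 0.11 and BDKRB2 by 0.76 ± 0.17 (limma adjusted p = 7.89e-04 and 0.0151 with the trend). The chemokine receptor CXCR4 lay at 2.30 ± 0.43 from a dim untreated signal of 29.8 ± 22.0 (SD, n = 3; adjusted p = 0.0320 by limma with the trend), and its ligand CXCL12 lay at -1.07 ± 0.11 (limma adjusted p = 1.04e-04 with the trend). F2RL2, PROCR, BDKRB1, BDKRB2, CXCR4 and CXCL12 all missed the threshold of limma without the trend (adjusted p = 0.0513, 0.0607, 0.115, 0.244, 0.172 and 0.0607), and over all alternatives their adjusted p ranged from 1.04e-04 to 0.517.

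GUCY1A1, the partner subunit of GUCY1B1, lay at -1.30 ± 0.14 by its brightest probe set, and the phosphodiesterases PDE9A and PDE4B at -1.34 ± 0.19 and -1.07 ± 0.11, while PDE8A lay at 0.93 ± 0.12 (limma adjusted p = 0.00148, 0.0403, 3.62e-04 and 3.03e-04 with the trend). A dimmer GUCY1A1 probe set was also lower without passing with the trend (limma adjusted p = 0.177). Among transcription factors, MEIS1, MEIS2 and GATA6 were lower, at -0.65, -0.70 and -0.86, and SALL1 and TBX3 were higher, at 0.91 and 0.68 (limma adjusted p = 0.0139, 0.00108, 0.00256, 2.09e-04 and 0.00571 with the trend). PGD, a dehydrogenase of the pentose phosphate pathway, was higher by 0.96 ± 0.11 (limma adjusted p = 1.04e-04 with the trend). Apart from GUCY1B1, none of the genes in this paragraph passed limma without the trend, the lowest adjusted p being 0.0607 for PDE4B, and over all alternatives their adjusted p ranged from 1.04e-04 to 0.517.

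BMP pathway genes were mostly lower with SHH, 9 of the 12 named, including the ligand BMP6 and the antagonists NOG, GREM1 and CHRDL1, while the ligand BMP2 and the antagonist FST were higher, at 0.87 and 0.69, and their direction against the other named genes did not pass (Fisher's exact two-sided p = 0.145, 0.546 after adjustment). The median difference of all probe sets was at most 0.0908 in size at any signal level, and the smallest of the 9, ID3, lay at -0.28. The list kept 3 higher and 9 lower after quantile normalization and after median centring, with medians of -0.53 and -0.45 against -0.54 before. Each of the 9 differences is larger than the largest median shift of 0.0908, but this comparison cannot decide on scaling between arrays. All members were named by their p in these samples. The smallest named member of any list was 0.23 in size, so none as small as the shift could be seen. The directions kept under both scalings add little for the same reason. Whether scaling affected which members were named stays open. Lower BMP signalling in the treated cells may be involved, and was asked of the ID genes, direct targets of the pathway, whose median log2 difference was -0.55. ID1 and ID4 were lower, at -0.87 and -0.83, and ID2 was higher, at 0.57 (limma adjusted p = 0.00283, 0.00895 and 0.00947 with the trend), so these genes leave it open.

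Bright probe sets were mostly higher with SHH: of 159 with a mean log2 signal of 12 or more that limma with an intensity trend called, 109 were higher, or 68.6% (exact 95% interval 60.7 to 75.7), against 51.6% of the 855 dimmer calls. Untreated replicate 1 has the lowest bright signals, and without it the share was 64.8% (interval 56.3 to 72.6) against 58.0% of dimmer calls (54.1 to 61.8), while it was 71.2% (60.05 to 80.8) against 60.7% (56.1 to 65.1) without replicate 2 and 71.6% (63.6 to 78.7) against 54.7% (50.6 to 58.7) without replicate 3. These intervals take the probe sets as independent, although all come from the same arrays, and so do not measure the spread between arrays. The intervals overlap without replicate 1 and without replicate 2, so whether replicate 1 alone gives the contrast stays open. After quantile normalization the share was 50.8% of 197 calls, but this step equalizes the bright ends of all arrays whatever the cause, so it does not separate a signal-dependent scaling difference from a rise of abundant transcripts with SHH. The deviations from the 6-array mean ranged over 0.21 among untreated and 0.03 among SHH arrays at a mean log2 of 13 or more, against a group difference of 0.08, and over 0.07 and 0.02 at 12 to 13, against a difference of 0.05 with all 3 SHH arrays above all 3 untreated arrays, so both cannot be told apart here.

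Of the 67 calls, 16 were dim, with a mean log2 signal under 7, among them FOXL1 and GGT5, an enzyme of the gamma-glutamyltransferase family whose signal went from 10.5 ± 1.82 to 280 ± 76.7 (SD, n = 3; log2 difference 3.45 ± 0.22, adjusted p = 0.0423 by limma). At that strictness most of them depended on a spread shared over all signal levels: at or under 6.09e-05, the largest unadjusted p among the 67, limma with an intensity trend kept 2 of the 16, FOXL1 and GGT5 (exact 95% interval of the share 1.55 to 38.3%), against 51 of the 51 brighter calls (93.0 to 100%), although 13 of the 16 pass the looser adjusted threshold of that fit, which calls 1014. All 67 were picked by their p without the trend, and the trend sets the spread by signal level. The contrast therefore cannot tell which fit is right for dim probe sets. Its intervals also take probe sets measured on the same arrays as independent. The pseudocount stays open: with a pseudocount of 1 limma kept 0 of the 16 but also 0 of the 51 (5009 probe sets at an unadjusted p under 0.05), while with the trend added 12 and 51 were kept. Whether their signal lies above background stays open too, because the value table has no detection calls; in 4 of the 16 the brighter group mean exceeded 105, the median signal of all arrays. The lower calls MSH4 and BTG4 had means of 70.2 and 60.9 in untreated and 6.24 and 9.26 in SHH-treated cells.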
